A study of Homo sapiens with 38 samples.

How the data were processed

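RNA levels were measured with Agilent one-colour human gene expression arrays in 5 triple-negative breast cancer cell lines, each as parental cells and as a paclitaxel-resistant derivative. The labels give 4 parental and 4 resistant samples for BT20, SUM149, MDA-MB-231 and MDA-MB-436, and 3 of each for MDA-MB-468, which makes 38 arrays in 10 groups. The labels describe independent RNA extractions from different cell passages, and for MDA-MB-468 independent replicates, but do not say which passage each sample came from. All cells were held without drug for 24 hours before harvest, and 100 ng of RNA was labelled with Cy3.

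Per the file headers, the deposited values are fluorescence intensities in scanner units on a linear scale, corrected for background and spatial trend by Agilent Feature Extraction and not normalized between arrays. The file headers name version 10.10.1.1 of that program, whereas the labels name version 8.1. The table of the whole series held the same values as the scanner files, with 0 values differing. Each array carried 62976 spots, of which 4259 were controls and were left out. Spots marked as outliers by the program, 234 to 924 per array, were left out as well, and 0 spots were saturated. The remaining spots formed 42405 probes. The scanner files give no gene names, so 25771 probes were named through their RefSeq transcript accession and 16634 stayed without a symbol, among them 1363 whose RefSeq accession had no match. Of the 34976 features, 19740 were gene symbols, and 4994 symbols had more than 1 probe.

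The log2 of each processed signal was taken, the log2 of that array's 75th percentile over the probes was subtracted, and spots of 1 probe were averaged. A gene was represented by its probe with the highest mean log2 signal over the 38 arrays. Fold changes were estimated with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading. A single linear model held a mean for each of the 10 groups, so that the spread between arrays was shared over the groups, and moderated statistics came from its empirical Bayes step. Tests were two-sided. A gene was tested in a line when its spot was well above background, by the scanner's own mark, on every array of at least 1 of the line's groups. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in the line, and genes with an adjusted p under 0.05 are called higher or lower in resistant cells. A second count adds a fold of 2 or more. Errors of log2 fold changes are standard errors from this model. A gene that was not well above background on any array of 1 group, by any of its probes, has a fold given as "at least". For this, dim arrays below the lowest signal of any probe well above background on that array were raised to that signal. Where every dim array already lay above it, nothing was raised and the fold is the fitted one, as for ARL14, SLPI, KRT6C and SLC10A4 below.

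The limits on precision are the number of arrays and the signal over background, since arrays have no counting depth. The 75th percentile ran from 916.5 to 2227.2 scanner units, the share of spots well above background from 62.2% to 79.2%, and the median local background from 40 to 66. Correlations between arrays of a group, across genes, ran from 0.942 to 0.9974. The p-values measure the spread between RNA extractions and arrays of 1 derivative of each line. They carry no spread between independently selected resistant derivatives.

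The 5 lines were read on 5 slides, with 1 line per slide, so slide and line cannot be told apart, and the comparison of states within a line stays within a slide. Parental and resistant arrays lay in different rows of the slide in every line except BT20, where both rows held both states. The replicate numbers of parental and resistant samples may stand for extractions made together, so the pairing was checked across genes after removing group means. Pairs with the same number correlated above 0.1 for all 4 numbers in SUM149 and MDA-MB-231 and all 3 in MDA-MB-468, for 3 of 4 in BT20, and for 2 of 4 in MDA-MB-436. In every line the number is also the column of the slide, so extraction pairs and columns cannot be told apart. Counts with the replicate number as a block are given beside the counts without it.

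Comparisons across lines used the same model. Genes called with a fold of 2 or more in the same direction in 3 or more lines were counted, and that count was set against 10000 permutations that shuffled the calls among the genes tested in each line. An F test over the lines asked whether the change differed between lines. A further limma fit took the 5 fold changes as 5 replicates. Correlations of fold changes between lines were computed across genes, which are not independent replicates. Expression within 2 Mb of ABCB1 was compared with runs of as many neighbouring genes elsewhere in the genome, by gene order in the reference annotation, as the share of runs whose median lay as high, doubled to cover both directions.

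The 33 gene lists covered ABC transporters linked to drug efflux, other ABC transporters, neighbours of ABCB1, tubulins, microtubule-associated proteins, the BCL2 family, mitosis, DNA replication, p53 targets, interferon-stimulated genes, MHC class I, MHC class II, NF-kB inflammatory genes, epithelial junctions, mesenchymal genes, keratins, luminal breast genes, stem-like cell markers, drug metabolism enzymes, NRF2 targets, cholesterol synthesis, the unfolded protein response, hypoxia with glycolysis, the EGFR family, AP-1 with immediate early genes, cancer-testis antigens, metallothioneins, replication-dependent histones, ribosomal proteins as a reference, and markers of leukocytes, endothelium, fibroblasts, and melanocytes with neural cells. They were tested with limma's camera at a preset correlation of 0.01 against the other genes tested in the line, adjusted over 165 tests, with an estimated correlation and with fry as alternatives.

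The comparisons, the lists and the rule for naming genes were fixed before the data were examined. Per line, the rule took ABCB1, the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, a fold of 2 or more, signal above background on every array and no overlap between groups, and the 4 rises and 4 falls with the highest bound among genes at background in 1 group. It also took up to 4 called members of each list by size of change, the genes shared by 4 or 5 lines, up to 8 per direction shared by 3 lines, and 6 genes with opposite calls. Unnamed and uncharacterised loci were counted but not named, and some genes that the rule names are not reported here.

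The alternatives were normexp background correction on the median spot and background signals with an offset of 50, quantile normalization, scaling by the median, no filter on dim genes, a stricter filter, a floor on low signals, the mean of a gene's probes, fits of each line alone, the replicate block, an intensity-dependent prior variance with robust estimation, the series table as source, other fold limits and windows, and leaving out each array and each line. The pipeline was tested on simulated data with 200 genes changed per line: 4-fold changes were recovered for 92.4% to 98.5% of genes, 2-fold changes for 61.2% to 80.6%, and 1.5-fold changes for 20.9% to 37.3%. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.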

Results

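The series compared parental cells of 5 triple-negative breast cancer lines with a paclitaxel-resistant derivative of each, to ask which genes differ once resistance to this microtubule-binding drug is in place. BT20, SUM149, MDA-MB-231 and MDA-MB-436 had 4 arrays per state and MDA-MB-468 had 3, and all cells had been without drug for 24 hours. The share of spots well above background ran from 62.2% to 79.2% per array. MDA-MB-231 parental arrays were dimmer than the resistant arrays of that line, with 75th percentiles of 916.5 to 1022.2 against 1286.7 to 1476.9 scanner units. Throughout, changes are resistant minus parental on the log2 scale with their standard error, and the number of arrays limits their precision. The standard error shares the spread over all 10 groups, so it can be too wide or too narrow for a single line. Where only part of the arrays of a state were well above background, the size of the change and its error are rough, and genes with 2 or fewer such arrays are marked. Arrays of the 2 states lay in different rows of the slide in every line except BT20, so row and state cannot be told apart in the other 4 lines.

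ABCB1, which encodes the drug efflux pump P-glycoprotein, rose in all 5 resistant derivatives. Its log2 fold change was 9.0 ± 0.56 in BT20 (adjusted p = 1.87e-13), 10.63 ± 0.56 in SUM149 (adjusted p = 5.88e-15). It was 6.74 ± 0.56 in MDA-MB-231 (adjusted p = 9.3e-11), 6.87 ± 0.56 in MDA-MB-436 (adjusted p = 5.02e-11) and 7.66 ± 0.65 in MDA-MB-468 (adjusted p = 1.37e-10). Every resistant array was well above background, with processed signals from 500.6 to 1302 in MDA-MB-436 up to 4680 to 13420 in BT20. Parental arrays were at background, between 3.69 and 15.2 scanner units, except the parental 2 array of BT20, which read 233 and was well above background. The fitted folds rest on signals at background, and with normexp background correction the log2 fold changes were 6.18, 6.66, 3.33, 3.82 and 5.02 in these 5 lines. The signals bound the rise at at least 749-fold in SUM149, 67.6-fold in MDA-MB-231, 98.7-fold in MDA-MB-436 and 195-fold in MDA-MB-468. In BT20 the rise was at least 393-fold with the parental 2 array and at least 796-fold without it.

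A further ABCB1 probe was also at background on the other parental arrays, and bounded the rise at at least 181-fold in BT20, 275-fold in SUM149, 50.3-fold in MDA-MB-231, 22.7-fold in MDA-MB-436 and 34.8-fold in MDA-MB-468. It read 58.9 on the BT20 parental 2 array. The fitted ABCB1 rises differed between the lines (F = 8.42, adjusted p = 0.000396), but this test rests on parental signals at background and does not show that the size of the rise differed.

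**Figure D1:**
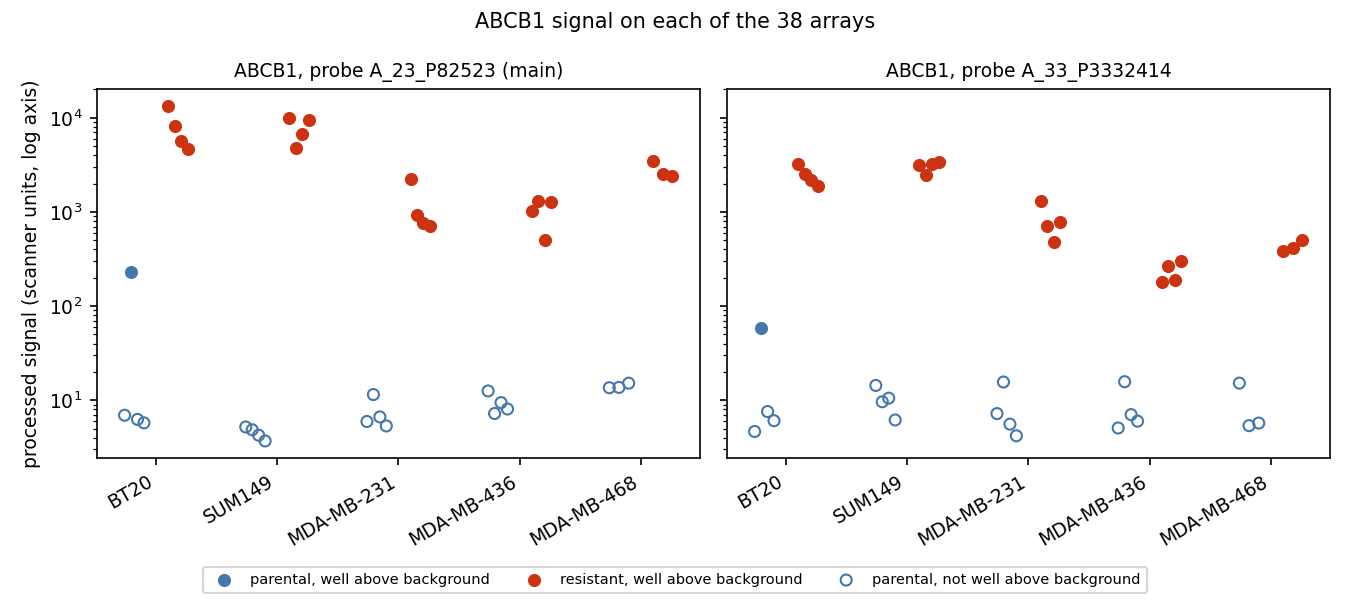
Processed signal of the 2 ABCB1 probes (scanner units, log axis) on each of the 38 arrays, by line, with parental arrays in blue and resistant arrays in red, and open circles for arrays not well above background. All resistant arrays lie above all parental arrays of their line, and the BT20 parental 2 array, at 233 on the main probe, lies between the groups.

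Genes beside ABCB1 on chromosome 7 rose with it in part of the lines. ABCB4, the neighbouring phospholipid transporter, rose at least 11.8-fold in BT20, 4.33-fold in MDA-MB-231 and 3.53-fold in SUM149, and was not tested in MDA-MB-436 and MDA-MB-468, where neither state had it well above background on every array. RUNDC3B rose at least 4.83-fold in BT20 and by 1.80 ± 0.41 in MDA-MB-436. CROT, an enzyme of peroxisomal fatty acid oxidation, rose by 1.49 ± 0.18 in BT20, 1.87 ± 0.18 in SUM149, 0.51 ± 0.18 in MDA-MB-436 and 1.18 ± 0.21 in MDA-MB-468. TMEM243 rose by 2.01 ± 0.59 in BT20 and 2.11 ± 0.59 in MDA-MB-231, and was 1.57 ± 0.59 in SUM149 (adjusted p = 0.0697). In SUM149 its arrays had standard deviations of 0.14 in parental and 0.15 in resistant cells, so the shared error of 0.59 is wide there. In MDA-MB-231 they were 2.28 and 0.51, with 3 of 4 parental arrays well above background, so the same error is narrow and that rise is uncertain. DBF4, a regulator of replication origins, rose by 1.16 ± 0.15 in SUM149, 0.74 in BT20 and 0.46 in MDA-MB-436 and fell by 0.87 in MDA-MB-231.

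Of the neighbours of ABCB1 tested, 9 of 12 were higher and 0 lower in BT20 (9 and 1 adjusted over the list alone; adjusted p = 2.06e-05, and adjusted p = 0.0215 with an estimated correlation). In SUM149, 4 of 10 were higher and 0 lower (5 and 0 adjusted over the list alone; adjusted p = 9.57e-06, and adjusted p = 0.0193 with an estimated correlation). The list was not called in MDA-MB-231 (adjusted p = 0.116), MDA-MB-436 (adjusted p = 0.495) or MDA-MB-468 (adjusted p = 0.0582). Within 2 Mb of ABCB1 the median change, ABCB1 itself left out, was 0.76 over 12 genes in BT20 and 0.70 over 10 genes in SUM149, and 1.13% and 0.693% of equally long runs of genes elsewhere lay as high, which doubled for both directions gives shares of 0.0226 and 0.0139. The medians in MDA-MB-231, MDA-MB-436 and MDA-MB-468 were 0.22, 0.21 and 0.21, with doubled shares of 0.419, 0.329 and 0.295. In every line the genes in this window were those of the neighbour list, so the window and the list are not independent evidence. With a window of 5 Mb the BT20 median was 0.28 and its share 0.116.

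**Figure D2:**
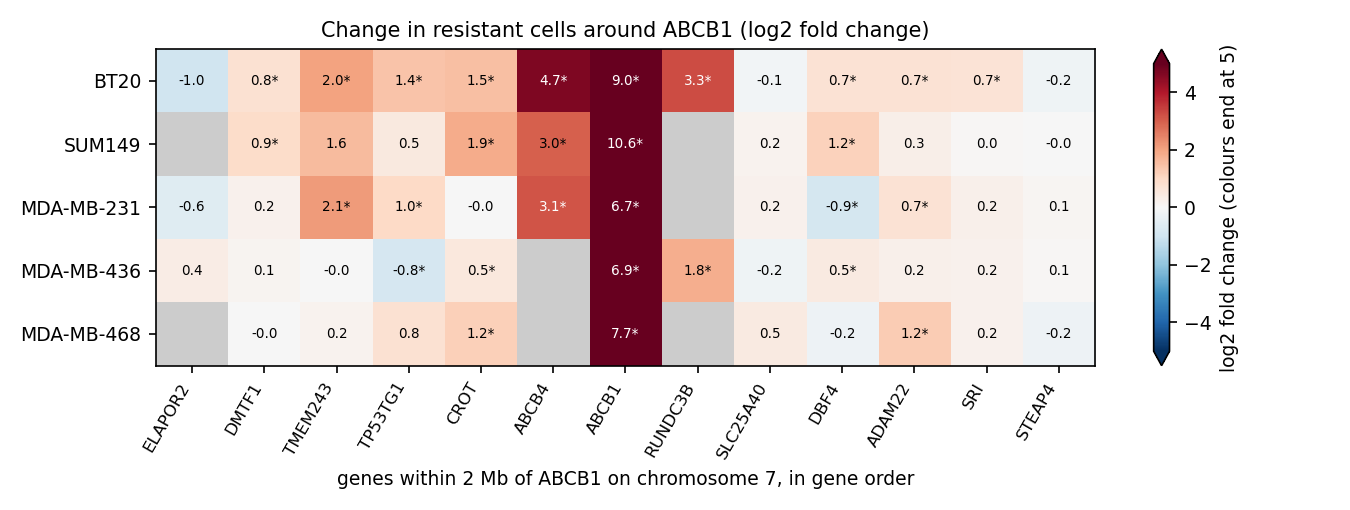
Log2 fold change, resistant minus parental, of ABCB1 and the genes around it in chromosome order (columns) in each line (rows), with grey for genes not tested and an asterisk for adjusted p under 0.05. BT20 and SUM149 have the highest medians of the neighbours, 0.76 and 0.70, colours end at 5, and ABCB1 exceeds every neighbour in all 5 lines.

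In BT20 resistant cells IFI44L rose by 5.37 ± 0.44, MX1 by 5.29 ± 0.41 and OAS2 by 4.25 ± 0.30, all induced by interferon. CALB2 (calretinin, a calcium-binding protein) rose by 5.07 ± 0.36, and ANXA1 (annexin A1) by 4.57 ± 0.20. XAF1 rose by 3.93 ± 0.41, COL4A6 (a basement membrane collagen chain) by 3.92 ± 0.37 and EREG (an EGFR ligand) by 3.89 ± 0.44. ACTG2 and ACTA2, the smooth muscle actins, had changes of -7.28 ± 0.63 and -3.96 ± 0.32, and CALD1, an actin-binding protein, -3.23 ± 0.40. MUCL1 (-4.57 ± 0.52), KRT1 (-4.37 ± 0.44), RAMP1 (-4.16 ± 0.51), FSTL1 (-3.51 ± 0.17) and HSD17B2 (-3.06 ± 0.39) fell as well. The groups of arrays did not overlap for any of these genes (4 against 4). AADACP1 rose at least 44.9-fold from background and PLAT (tissue plasminogen activator) at least 26.5-fold, and ARL14 rose by a fitted 28.3-fold. The cancer-testis genes FMR1NB and PASD1 fell to background, at least 1270-fold and 498-fold, as did ZNF22 at least 108-fold and DPYSL5 at least 77.4-fold.

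In the BT20 lists, 38 of 41 interferon-stimulated genes were higher and 0 lower (39 and 0 adjusted over the list alone), with a median of 2.02, led by IFI44, well above background on 2 of 4 parental arrays, at 6.07 ± 0.56 (adjusted p = 2.69e-35, and adjusted p = 0.0193 with an estimated correlation). This list and the neighbours of ABCB1 were the BT20 lists called with an estimated correlation. MHC class I genes, which present antigen, had 12 of 19 higher (12 higher and 1 lower adjusted over the list alone), among them ERAP2 at 1.55 ± 0.19 and B2M at 0.94 ± 0.18 (adjusted p = 2.39e-05, and adjusted p = 0.49 with an estimated correlation). MHC class II genes had 6 of 12 lower (7 adjusted over the list alone), with HLA-DRA at -2.00 ± 0.61 and HLA-DPB1 at -1.97 ± 0.47 (adjusted p = 0.0121, and adjusted p = 0.622 with an estimated correlation). Among NF-kB inflammatory genes 10 of 27 were higher (12 adjusted over the list alone), with CXCL8 at 4.15 ± 0.66 and IL1B at 3.52 ± 0.57, well above background on only 2 and 1 of 4 parental arrays (adjusted p = 9.42e-05, and adjusted p = 0.544 with an estimated correlation). Mitosis genes had 16 of 32 higher (21 higher and 2 lower adjusted over the list alone), with PLK1 at 1.46 ± 0.29 and PTTG1 at 1.37 ± 0.22 (adjusted p = 1.61e-05, and adjusted p = 0.569 with an estimated correlation). Cholesterol synthesis genes had 6 of 22 lower and 2 higher (7 and 2 adjusted over the list alone), with IDI1 at -1.16 ± 0.23 (adjusted p = 0.0245, and adjusted p = 0.695 with an estimated correlation). Cancer-testis antigens had 4 of 14 lower (7 lower and 1 higher adjusted over the list alone), with MAGEA6 at -1.06 ± 0.17 (adjusted p = 0.0209, and adjusted p = 0.176 with an estimated correlation). The efflux transporters had 5 of 12 higher and 2 lower (5 and 2 adjusted over the list alone), with ABCC4 at least 4.98-fold higher beside ABCB1 and ABCB4, and ABCC5 at -1.36 ± 0.16 (adjusted p = 0.0155, and adjusted p = 0.176 with an estimated correlation). Their median was 0.30 against a mean of 1.45, which ABCB1 lifts, so this call is not independent of ABCB1.

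In BT20, 5250 of 23747 genes tested were called (22.1%), 2824 higher and 2426 lower, and 1009 rises and 602 falls were 2-fold or more. The groups did not overlap for 4729 genes (19.9%, against 2.86% by chance). The replicate block gave 6096 genes, of which 5064 were also called without it. A fit of the 8 BT20 arrays alone called 3084 genes, and 1808 with the row of the slide as a term.

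In SUM149 resistant cells FDCSP rose by 4.56 ± 0.48, RNF144A by 3.36 ± 0.40 and OLAH by 3.30 ± 0.39. PTGER4 (a prostaglandin E2 receptor) rose by 3.27 ± 0.37, TLR4 (the lipopolysaccharide receptor) by 3.15 ± 0.45, HHIP (a hedgehog inhibitor) by 3.12 ± 0.53, IGFBP2 by 3.07 ± 0.28 and CXCL8 (a neutrophil chemokine) by 3.05 ± 0.66. LTF (lactoferrin) changed by -5.74 ± 0.81, EDN2 (endothelin 2) by -5.03 ± 0.28, SYT12 by -4.19 ± 0.38 and CCR2 by -4.03 ± 0.62. The LTF arrays had standard deviations of 2.75 in parental and 1.92 in resistant cells, so its shared error is narrow for this line. CFI (complement factor I) changed by -3.89 ± 0.49, CYP4B1 by -3.71 ± 0.56, SPINK6 by -3.50 ± 0.37 and ABLIM3 by -3.47 ± 0.23. The arrays of the groups did not overlap for these genes (4 against 4). From background, PDIA2 rose at least 45.4-fold, IRX4 13.1-fold and IL1RL1 12.6-fold. To background, ACKR3 fell at least 26.7-fold, OLFM4 24.4-fold, NPTX1 24-fold and BMPER 21.4-fold.

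NF-kB inflammatory genes had 15 of 37 higher and 0 lower in SUM149 (17 and 0 adjusted over the list alone), with CSF3 at 4.20 ± 0.69, IL6 at 2.96 ± 0.61 and CSF2 at least 5.35-fold higher (adjusted p = 1.27e-05, and adjusted p = 0.542 with an estimated correlation). Interferon-stimulated genes went both ways, 6 of 41 higher and 9 lower (8 and 11 adjusted over the list alone; adjusted p = 0.794), with ISG20 at 1.60 ± 0.22 and IFI44L at -1.83 ± 0.44. AP-1 and immediate early genes had 9 of 24 higher and 3 lower (10 and 3 adjusted over the list alone), with ANKRD1 at least 10.7-fold higher and PHLDA1 at 1.90 ± 0.62 (adjusted p = 0.0193, and adjusted p = 0.569 with an estimated correlation). Cholesterol synthesis had 7 of 24 higher (12 adjusted over the list alone), with HMGCS1 at 1.81 ± 0.32 (adjusted p = 9.14e-05, and adjusted p = 0.562 with an estimated correlation). In the list of mitosis genes 2 of 32 were higher (2 adjusted over the list alone), with CCNB1 at 0.89 ± 0.21 (adjusted p = 0.000245, and adjusted p = 0.683 with an estimated correlation). In that of DNA replication 5 of 32 were higher (5 adjusted over the list alone), with CCND1, which encodes cyclin D1, at 2.34 ± 0.16 (adjusted p = 0.000357, and adjusted p = 0.683 with an estimated correlation). The tubulins, the targets of paclitaxel, had 2 of 18 higher (1 adjusted over the list alone), with TUBB2A at 0.82 ± 0.24 (adjusted p = 0.00815, and adjusted p = 0.311 with an estimated correlation). The unfolded protein response had 6 of 25 higher (6 adjusted over the list alone), with ATF3 at 1.47 ± 0.36 (adjusted p = 0.0115, and adjusted p = 0.544 with an estimated correlation). Drug metabolism enzymes had 9 of 31 lower and 3 higher (9 and 3 adjusted over the list alone), with CYP2J2 at -2.54 ± 0.31, CYP24A1 at 2.12 ± 0.38 and GSTM3 at -1.50 ± 0.33 (adjusted p = 0.0193, and adjusted p = 0.218 with an estimated correlation). The efflux transporters had 4 of 12 higher (4 higher and 1 lower adjusted over the list alone), with ABCA3 at 0.90 ± 0.23 beside ABCB1 and ABCB4 (adjusted p = 0.0272, and adjusted p = 0.188 with an estimated correlation). Their median was 0.21 against a mean of 1.17, which ABCB1 lifts, so this call is not independent of ABCB1. Ribosomal protein genes, the reference list, had 8 of 40 lower (8 adjusted over the list alone), and their median of -0.16 was -0.06 after quantile normalization (adjusted p = 0.000245, and adjusted p = 0.683 with an estimated correlation).

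In SUM149, 3669 of 24630 genes tested were called (14.9%), 2057 higher and 1612 lower, and 537 rises and 508 falls were 2-fold or more. The groups did not overlap for 7020 genes (28.5%, against 2.86% by chance). The replicate block gave 4408 genes, of which 3482 were also called without it, and a fit of the 8 arrays alone gave 6742.

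In MDA-MB-231 resistant cells CCL3 (a macrophage chemokine) rose by 5.26 ± 0.52, C3 (complement) by 4.62 ± 0.60, DMKN by 4.36 ± 0.37, ABCC3 (an efflux transporter) by 4.34 ± 0.47, COL4A4 by 4.29 ± 0.32 and DPP4 by 4.21 ± 0.39. GBP5 and GBP2, guanylate-binding proteins induced by interferon, rose by 4.71 ± 0.47 and 4.16 ± 0.46. PAGE2B and PAGE2, of a cancer-testis family, changed by -5.53 ± 0.62 and -5.35 ± 0.66, and KHDRBS3 (an RNA-binding protein) by -5.17 ± 0.56. LDOC1 changed by -4.93 ± 0.53, SLCO4A1 by -4.57 ± 0.35, ZC4H2 by -4.24 ± 0.36, CPVL by -3.78 ± 0.50 and F2RL2 by -3.78 ± 0.54. The arrays of the groups did not overlap for these genes (4 against 4). FAP, a protease of activated fibroblasts, rose at least 48.5-fold from background and GPR143 at least 15.2-fold, and SLPI rose by a fitted 31.8-fold. CALHM2 fell to background at least 99.6-fold, ZNF521 90.1-fold, NRK 84.2-fold and ATP10A 65.6-fold.

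NF-kB inflammatory genes had 29 of 37 higher and 3 lower in MDA-MB-231 (30 and 3 adjusted over the list alone), with a median of 2.34, CCL5 at 4.77 ± 0.54 (well above background on 1 of 4 parental arrays) and LCN2 at 4.24 ± 0.75, while PTGS2 was at least 27.3-fold lower (adjusted p = 1.02e-10, and adjusted p = 0.213 with an estimated correlation). Interferon-stimulated genes had 31 of 42 higher and 1 lower (32 and 1 adjusted over the list alone), with OAS1 at least 15.1-fold higher and MX1 at 3.16 ± 0.41 (adjusted p = 1.74e-13, and adjusted p = 0.188 with an estimated correlation). MHC class I genes had 16 of 19 higher and 1 lower (16 and 1 adjusted over the list alone), with HLA-F at 2.40 ± 0.55 and B2M at 1.77 ± 0.18 (adjusted p = 9.04e-06, and adjusted p = 0.436 with an estimated correlation). Fibroblast markers had 5 of 9 higher (5 adjusted over the list alone): FAP, PDGFRB at 4.44 ± 0.41, LUM at 3.59 ± 0.36, COL1A2 at 2.62 ± 0.43 and COL1A1 at 1.47 ± 0.30 (adjusted p = 0.000863, and adjusted p = 0.0408 with an estimated correlation). LUM and COL1A2 were each well above background on 1 of 4 parental arrays. The mesenchymal list is not independent of the fibroblast markers, sharing PDGFRB, LUM, COL1A2, COL1A1 and S100A4 among the genes tested here and COL3A1, DCN, POSTN, THY1, PRRX1 and TWIST2 besides. It had 16 of 27 higher and 1 lower (18 and 2 adjusted over the list alone; adjusted p = 2.81e-05, and adjusted p = 0.0755 with an estimated correlation). Epithelial junction genes also had 10 of 24 higher and 1 lower (10 and 1 adjusted over the list alone), with SPINT1 at 5.52 ± 0.39 (well above background on 1 of 4 parental arrays) and CDS1 at 1.96 ± 0.16 (adjusted p = 0.000245, and adjusted p = 0.188 with an estimated correlation). Mitosis genes had 25 of 32 lower and 0 higher (25 and 0 adjusted over the list alone), with CDC20 at -1.57 ± 0.21 and PLK1 at -1.55 ± 0.29 (adjusted p = 4.67e-06, and adjusted p = 0.562 with an estimated correlation). The BCL2 family of cell death regulators had 7 of 18 higher and 2 lower (7 and 2 adjusted over the list alone), with BMF at 3.17 ± 0.46 and HRK at least 3.12-fold higher, both promoters of cell death (adjusted p = 0.0332, and adjusted p = 0.176 with an estimated correlation). NRF2 targets, genes of the oxidative stress response, had 12 of 24 higher and 3 lower (12 and 3 adjusted over the list alone), with AKR1C1 at 2.29 ± 0.51 (adjusted p = 0.031, and adjusted p = 0.683 with an estimated correlation). Ribosomal protein genes had 28 of 40 lower (29 lower and 1 higher adjusted over the list alone), and their median of -0.42 was -0.07 after quantile normalization (adjusted p = 1.61e-07, and adjusted p = 0.544 with an estimated correlation).

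In MDA-MB-231, 9650 of 23889 genes tested were called (40.4%), 4128 higher and 5522 lower, and 1902 rises and 1050 falls were 2-fold or more. The groups did not overlap for 8084 genes (33.8%, against 2.86% by chance). The replicate block gave 10639 genes, of which 9396 were also called without it. When the arrays of this line were split otherwise, the splits that set parental 1 apart from the other parental arrays called 2244 to 3625 genes. No other split apart from the real one called more than 914, so parental 1 differed from the other parental arrays. The median change of all genes tested was -0.10 and became -0.19 with normexp background correction, under which 3491 genes were higher and 7555 lower, so that the share of called genes that were higher fell from 42.8% to 31.6%.

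In MDA-MB-436 resistant cells LY6D, a surface protein of squamous epithelia, rose by 7.22 ± 0.43, SERPINB5 (maspin) by 6.94 ± 0.34, and KRT6A by 6.18 ± 0.66. SFN (14-3-3 sigma) rose by 4.28 ± 0.43, LRRC38 by 4.23 ± 0.26, KRT16P2 by 3.86 ± 0.45, KRT14 by 3.65 ± 0.51 and SPANXA1 by 3.53 ± 0.71. H4C5 (a histone H4 gene) changed by -7.18 ± 0.38, BZW2 by -6.74 ± 0.15, and OCIAD2 by -6.37 ± 0.19. CYP1B1 (an oestrogen-metabolizing enzyme) changed by -5.93 ± 0.54, FDCSP by -5.24 ± 0.48 and BEX1 by -5.14 ± 0.25. The interleukin genes IL1B and IL1A changed by -6.47 ± 0.57 and -6.00 ± 0.56. The arrays of the groups did not overlap for these genes (4 against 4). PCDHA1 rose at least 114-fold from background and SLCO1B3 (an uptake transporter) at least 45.1-fold, and KRT6C rose by a fitted 67.9-fold. To background, CCL7 fell at least 69.4-fold, SERPINB2 67.7-fold and OLR1 33-fold, and SLC10A4 fell by a fitted 44.3-fold.

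Keratins had 6 of 19 higher and 0 lower in MDA-MB-436 (7 and 0 adjusted over the list alone), with KRT16 at 3.44 ± 0.48 beside KRT6A, KRT6C and KRT14 (adjusted p = 0.0098, and adjusted p = 0.562 with an estimated correlation). NF-kB inflammatory genes had 21 of 37 lower and 2 higher (22 and 3 adjusted over the list alone), with a median of -1.73, CCL2 at -8.51 ± 0.50 and CSF3 at -4.28 ± 0.69 (adjusted p = 9.87e-11, and adjusted p = 0.213 with an estimated correlation). Interferon-stimulated genes had 16 of 42 higher and 4 lower (20 and 5 adjusted over the list alone), with IFIT3 at 2.35 ± 0.32, IFIT1 at 2.22 ± 0.39 and BST2 at -2.99 ± 0.14 (adjusted p = 0.0155, and adjusted p = 0.692 with an estimated correlation). Cholesterol synthesis had 8 of 23 higher (10 adjusted over the list alone), with TM7SF2 at 1.22 ± 0.30 and IDI1 at 1.21 ± 0.21 (adjusted p = 0.00681, and adjusted p = 0.683 with an estimated correlation). Ribosomal protein genes had 14 of 40 higher (16 adjusted over the list alone), and their median of 0.17 turned to -0.01 after quantile normalization (adjusted p = 1.85e-06, and adjusted p = 0.562 with an estimated correlation).

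In MDA-MB-436, 5422 of 25666 genes tested were called, 2978 higher and 2444 lower, and 1222 rises and 896 falls were 2-fold or more. The groups did not overlap for 8428 genes (32.8%, against 2.86% by chance). The replicate block gave 6183 genes, of which 5253 were also called without it.

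In MDA-MB-468 resistant cells H19, an imprinted long noncoding RNA, rose by 7.35 ± 0.43, WFDC2 by 5.34 ± 0.31, IFI27L2 by 4.98 ± 0.24, ALDH1A1 (retinaldehyde dehydrogenase) by 4.65 ± 0.27. NNMT (nicotinamide methyltransferase) rose by 4.41 ± 0.58, PALM by 4.40 ± 0.36, SERPINA1 (antitrypsin) by 4.29 ± 0.34 and CCDC3 by 4.21 ± 0.92. VAV1, a guanine nucleotide exchange factor of blood cells, changed by -5.37 ± 0.29, RASIP1 by -3.76 ± 0.25, NR2F1 by -3.60 ± 0.39, and CSF1R by -3.57 ± 0.35. CA9 (a hypoxia-induced carbonic anhydrase) changed by -3.50 ± 0.41, NPNT by -3.26 ± 0.52, VNN1 by -3.16 ± 0.69 and ACP5 by -3.14 ± 0.30. The arrays of the groups did not overlap for these genes (3 against 3). CALB2 rose at least 51-fold from background, NGFR (the low-affinity nerve growth factor receptor) 46-fold and SERPINB2 40.1-fold. To background, GNG11 fell at least 110-fold, SDHAF3 56.6-fold, PDLIM3 33.3-fold and MT1M 28.9-fold.

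MHC class II genes had 5 of 10 higher and 0 lower in MDA-MB-468 (6 and 0 adjusted over the list alone), with HLA-DPB1 at least 30.7-fold higher, HLA-DPA1 at 3.80 ± 0.30 and CIITA, their main transcription activator, at 3.00 ± 0.63 with 1 of 3 parental arrays well above background (adjusted p = 0.000261, and adjusted p = 0.444 with an estimated correlation). MHC class I had 6 of 19 higher (7 adjusted over the list alone), with HLA-C at 0.89 ± 0.31 (adjusted p = 0.0296, and adjusted p = 0.683 with an estimated correlation). Interferon-stimulated genes had 12 of 42 higher and 1 lower (15 and 1 adjusted over the list alone), with IFIT1 at 1.73 ± 0.45, XAF1 at 1.73 ± 0.47 and BST2 at -1.19 ± 0.16 (adjusted p = 7.16e-05, and adjusted p = 0.562 with an estimated correlation). Cholesterol synthesis had 11 of 24 lower and 0 higher (11 and 0 adjusted over the list alone), with INSIG1 at -1.34 ± 0.49 (adjusted p = 0.00943, and adjusted p = 0.683 with an estimated correlation). Hypoxia and glycolysis genes had 9 of 27 lower and 1 higher (9 and 1 adjusted over the list alone), with VEGFA at -1.92 ± 0.27 beside CA9 and SLC2A3 at 1.56 ± 0.43 with 1 of 3 parental arrays well above background (adjusted p = 0.0282, and adjusted p = 0.683 with an estimated correlation). Mitosis genes had 5 of 32 lower (5 adjusted over the list alone), with CENPF at -0.83 ± 0.29 (adjusted p = 0.0162, and adjusted p = 0.765 with an estimated correlation). Keratins had 5 of 19 higher (5 adjusted over the list alone), with KRT13 at 1.96 ± 0.31 and KRT4 at 1.55 ± 0.32 (adjusted p = 0.00851, and adjusted p = 0.562 with an estimated correlation). The BCL2 family had 5 of 19 higher (5 adjusted over the list alone), with BMF at 2.28 ± 0.53 and BCL2L1, an inhibitor of cell death, at 1.38 ± 0.24 (adjusted p = 0.0347, and adjusted p = 0.176 with an estimated correlation). Drug metabolism enzymes had 7 of 25 higher and 2 lower (7 and 2 adjusted over the list alone), with CYP24A1 at least 15.5-fold higher and CYP1A1 at 3.82 ± 0.47 (adjusted p = 0.0316, adjusted p = 0.339 with an estimated correlation and adjusted p = 0.0833 with the replicate block). Endothelial markers had 3 of 7 higher (3 adjusted over the list alone), KDR at 1.94 ± 0.35, VWF at 1.39 ± 0.23 (well above background on 1 of 3 parental arrays) and EGFL7 at 1.06 ± 0.20 (adjusted p = 0.0329, adjusted p = 0.213 with an estimated correlation and adjusted p = 0.0599 with the replicate block).

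In MDA-MB-468, 4730 of 20512 genes tested were called (23.1%), 2009 higher and 2721 lower, and 973 rises and 689 falls were 2-fold or more. The groups did not overlap for 7654 genes (37.3%, against 10% by chance). The replicate block gave 5516 genes, of which 4523 were also called without it, and a fit of the 6 arrays alone gave 2605. The median change of all genes tested was -0.10, and the share of called genes that were higher was 42.5% and became 52.2% after quantile normalization.

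Over the 33 lists and 5 lines, 45 of 165 tests were called, 34 higher and 11 lower, and 4 of the 45 with an estimated correlation. When the arrays of each line were split at random into groups of the same sizes, a median of 28 and at most 42 of the 165 tests were called. Splits that leave 3 of 4 arrays of a state together keep part of the contrast. Median, mean and test had the same sign in every called list, and differed in sign in 28 of the 120 tests not called. The median of 1 called list, the ribosomal proteins of MDA-MB-436, changed sign under another scaling.

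The other lists were not called in any line. Their medians ran from -0.03 to 0.16 for other ABC transporters, -0.13 to 0.10 for microtubule-associated proteins, -0.16 to 0.23 for p53 targets, -0.15 to 0.19 for luminal breast genes, -0.15 to 0.44 for stem-like cell markers and -0.05 to 0.34 for the EGFR family. They ran from -0.86 to 0.14 for metallothioneins, -0.61 to 0.27 for replication-dependent histones, -0.41 to 0.03 for leukocyte markers and -0.14 to 0.17 for melanocyte and neural markers. With the replicate block, metallothioneins were called lower in SUM149 (adjusted p = 0.0384, against 0.063 without it) and histones lower in MDA-MB-231 (adjusted p = 0.0129, against 0.063). Single members of these lists passed the test, among them MAP2 at -5.67 ± 0.69 in SUM149, TPPP at 4.10 ± 0.55 in MDA-MB-231 (well above background on 1 of 4 parental arrays), and STMN2, which destabilizes microtubules, at least 18.9-fold higher in MDA-MB-436.

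**Figure D3:**
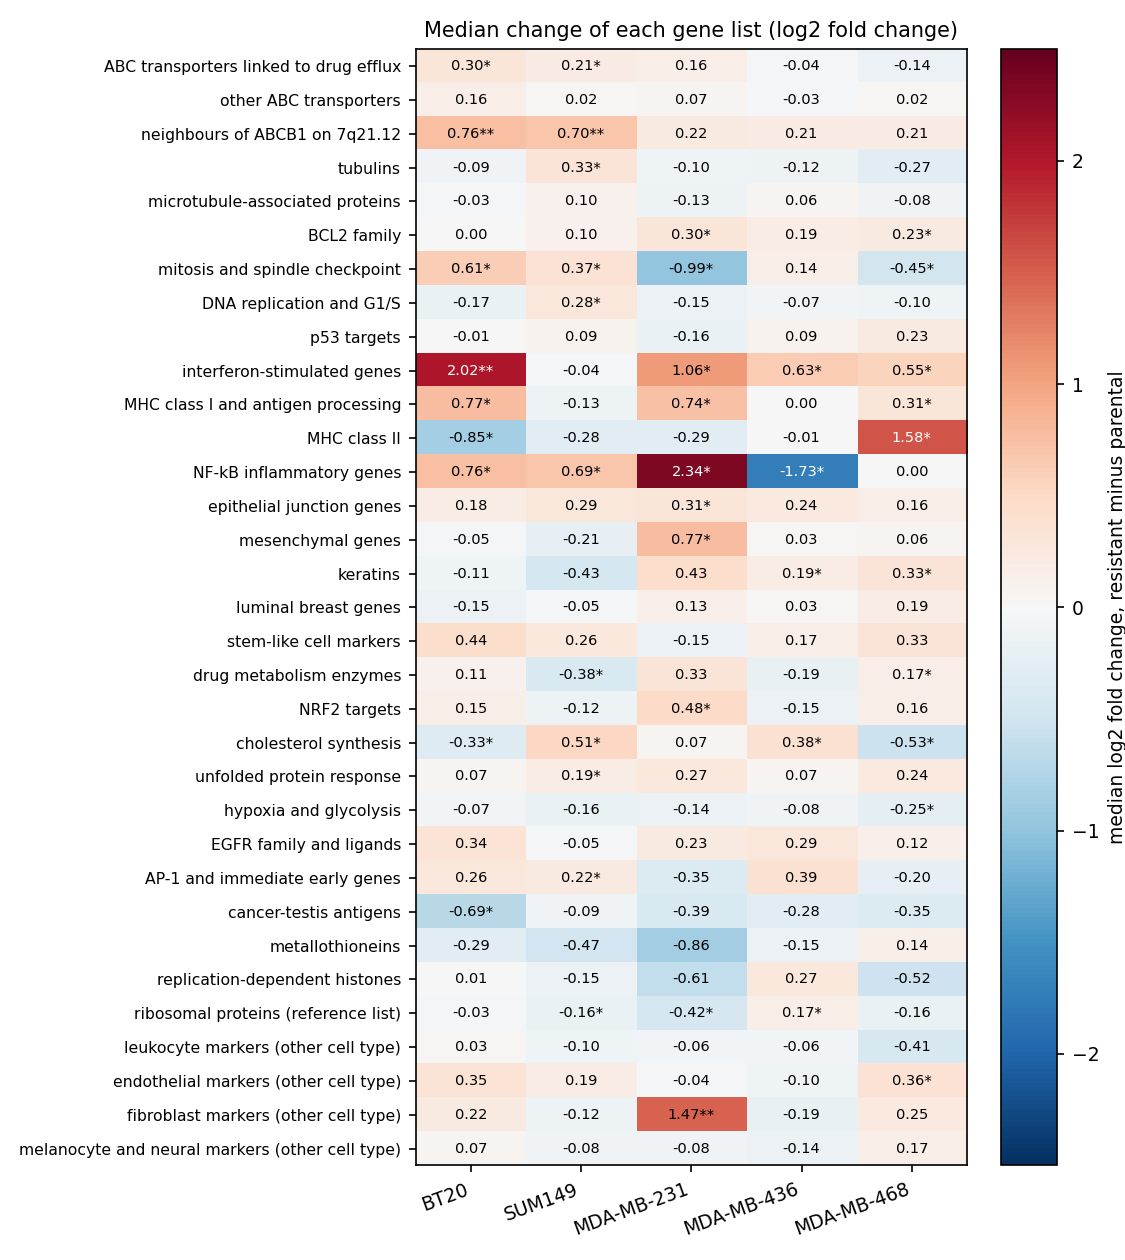
Median log2 fold change, resistant minus parental, of each gene list (rows) in each line (columns), with 1 asterisk for lists called by camera and 2 for those called with an estimated correlation as well. Interferon-stimulated genes run from -0.04 in SUM149 to 2.02 in BT20, and the ribosomal list of MDA-MB-436, at 0.17, turns to -0.01 after quantile normalization.

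**Figure D4:**
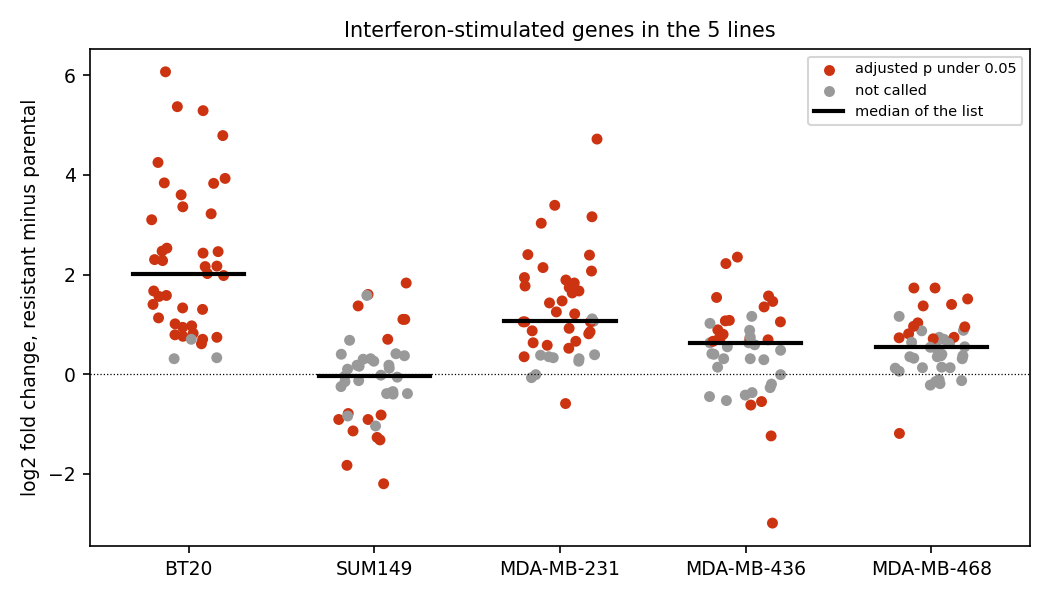
Log2 fold change, resistant minus parental, of each interferon-stimulated gene (points) in the 5 lines, with red points for adjusted p under 0.05, grey points for the rest and a bar at the median. In BT20 38 of 41 and in MDA-MB-231 31 of 42 members were higher, and in SUM149 6 were higher and 9 lower.

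A further comparison asked which genes changed alike across the lines. ABCB1, TNFSF9 (the ligand of the T cell receptor 4-1BB) and HERC6 (an interferon-induced ubiquitin ligase) were higher by 2-fold or more in all 5 lines, TNFSF9 by 1.42 ± 0.28 in MDA-MB-468 to 2.03 ± 0.24 in BT20 and HERC6 by 1.08 ± 0.23 in MDA-MB-436 to 2.28 ± 0.23 in BT20. In 4 lines the interferon-induced genes RTP4 and ISG20, INHBA (a subunit of activin), TMC8, LAMP3 and PCDHB14 were higher. HOXB6, NOG (a BMP inhibitor), CTHRC1, CLDN1 (a tight junction protein) and 2 features without a symbol were also higher in 4 lines. INHBA rose by 3.26 ± 0.55 in MDA-MB-468 and was -0.44 ± 0.48 in MDA-MB-436, and CTHRC1 fell by 1.26 in BT20. CFI and SPDEF, a luminal transcription factor, were lower in 4 lines. CFI changed by -5.97 ± 0.49 in MDA-MB-436 and by 1.27 ± 0.49 in MDA-MB-231, and SPDEF by -2.59 ± 0.30 in MDA-MB-231 and 0.12 ± 0.30 in MDA-MB-436. Genes higher in 3 lines included ABCB4, RYR2, CXCL8, SORCS2, SERPINB3, SERPINB4, LY6D and BDKRB1. Genes lower in 3 lines included CA9, ABAT, OLFM4, CPVL, RBPMS, RTL8B and BICD1.

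In all, 153 features were higher (130 with a symbol) and 29 lower (25 with a symbol) by 2-fold or more in 3 or more lines. Shuffling the calls among the tested genes of each line gave a mean of 18.6 and at most 37 higher, and a mean of 5.89 and at most 17 lower (permutation p = 1e-04 for each, the smallest that 10000 permutations can give). The shuffle takes calls as independent between lines, so it cannot part a shared direction from genes prone to change either way. Of the 2-fold rises in BT20, 221 were also rises in MDA-MB-231 and 61 were falls there. Of those in MDA-MB-231, 141 were rises in MDA-MB-436 and 222 were falls there. Of the shared rises, 10 were interferon-stimulated genes, 5 NF-kB inflammatory genes and 2 efflux transporters, and the tubulin TUBB2B was 1. Of the shared falls, 2 were luminal breast genes and 1 was a hypoxia gene. The count of 182 became 76 with normexp background correction, 94 under a stricter filter on dim genes and 85 without MDA-MB-231.

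**Figure D5:**
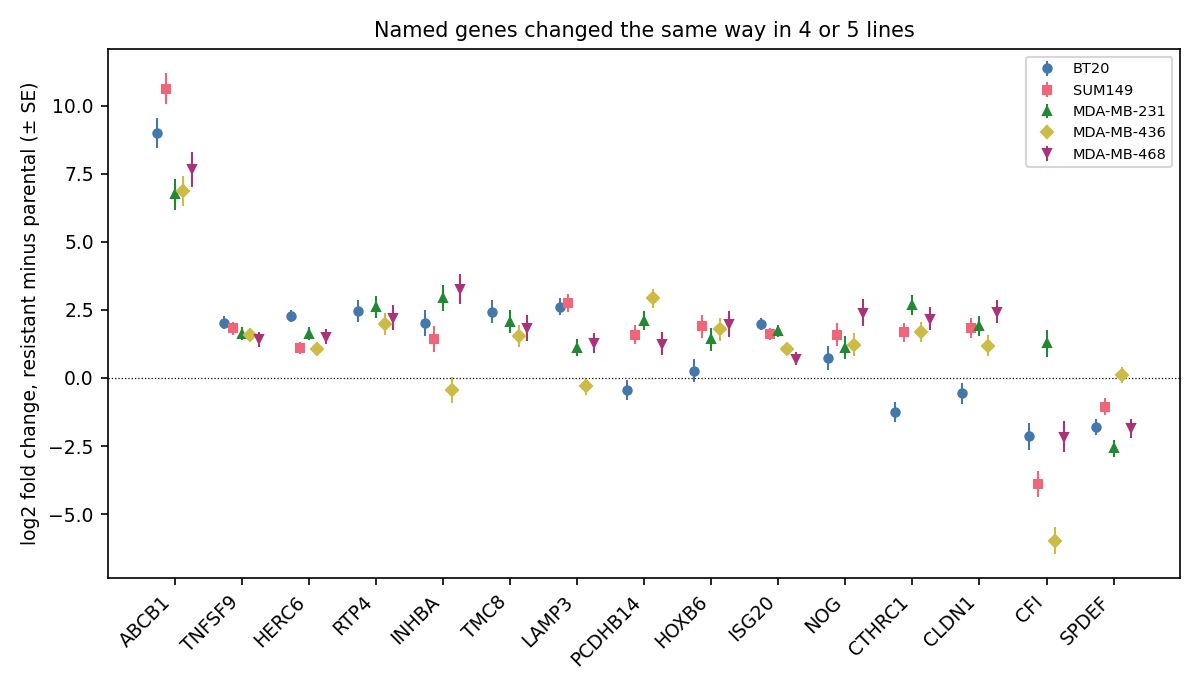
Log2 fold change, resistant minus parental, with its standard error, of the named genes that changed alike in 4 or 5 lines, with a symbol for each line and none where the gene was not tested. ABCB1, TNFSF9 and HERC6 are higher in all 5 lines, and CFI and SPDEF are lower in 4.

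With the 5 fold changes taken as 5 replicates, limma called 2 of 18603 genes, ABCB1 with a mean of 8.18 ± 0.57 and TNFSF9 with 1.70 ± 0.13, both higher in 5 of 5 lines (adjusted p = 0.0373 for each), and 1189 genes had an unadjusted p under 0.05. No gene was called with normexp background correction, quantile normalization, no filter on dim genes or an intensity-dependent prior variance with robust estimation, and 1 was under the stricter filter and without SUM149. No gene was called without any 1 of the lines BT20, MDA-MB-231, MDA-MB-436 or MDA-MB-468, or without the parental 2 array of BT20.

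Most changes differed between the lines. The change differed for 15281 of 27353 genes (55.9%), and of the 6993 genes called with 2-fold or more in at least 1 line, 5143 were so in exactly 1 and 989 went in opposite directions. ZNF22 fell to background in BT20 and was 1.02 ± 0.13 higher in MDA-MB-436 (F = 783). GNG11, a G protein subunit, fell to background in MDA-MB-468 and rose by 2.18 ± 0.19 in SUM149 (F = 361). DPYSL5 fell to background in BT20 and rose at least 27.4-fold in MDA-MB-468 (F = 263). AHR, the dioxin receptor, changed by -7.50 ± 0.28 in MDA-MB-436 and 1.44 ± 0.28 in SUM149 (F = 168), BST2 by -2.99 ± 0.14 in MDA-MB-436 and 1.33 ± 0.14 in BT20 (F = 135), and VIPR1 by -5.18 ± 0.25 in MDA-MB-436 and 2.19 ± 0.25 in BT20 (F = 126). In MDA-MB-436 AHR and VIPR1 were each well above background on only 1 of 4 resistant arrays, and VIPR1 on 2 of 4 parental arrays of BT20, so these sizes are rough. Across genes, which are not independent replicates, Pearson's correlation of the fold changes between 2 lines ran from -0.13 to 0.20 over the 10 pairs, with a median of 0.04, and Spearman's from -0.16 to 0.23, with a median of 0.06.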

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

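The tests of mixed samples, of a brighter array, of the share of another line that a gene would need and of scaling described here were chosen after the results they explain had been seen, and the other tests before. A sample lying far from the others of its group was found in 26 of 304 tests, each of 1 gene, probe or array value in 1 group of 4 arrays. Chance gives about 1 in 20 of such tests, which share arrays and so are not independent. The numbers after each array below are its gap to the nearest other array as a share of the group's range.

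ABCB1 lay far above the other parental arrays on 1 BT20 parental array (parental 2, 0.981), at -2.43 on the scaled log2 scale against -7.05 to -6.96. On the slide this array lay in row 2 with the other resistant arrays, and resistant 2 lay in row 1 with the other parental arrays. Whether that place bears on the ABCB1 signal was not tested. Parental 2 was the brightest BT20 array, with a 75th percentile of 1874.5 scanner units against 1081.1 to 1230.3 on the other parental arrays. Brightness lifting dim probes is argued against as the source of its ABCB1 signal. The 7830 genes not well above background elsewhere in the line had a median change of -0.24 on this array before scaling, against 5.21 for ABCB1. A swap with resistant 2 is argued against too, since over 1610 genes parental 2 lay 0.064 of the way from the parental to the resistant mean and resistant 2 lay 0.059 of the way from the resistant to the parental mean. Resistant RNA or cells mixed into that sample could give this signal at a share of 1.96%, and the 24 genes that this share would lift by over 0.5 rose by a median of 0.73 on that array, against 0.664 predicted and 0.239, -0.137 and -0.169 on the other parental arrays. Among brighter genes the rise was below the prediction for ANXA1 (0.21 against 0.53) and above it for MX1 (1.72 against 1.01) and CASP1 (3.92 against 0.66). Some genes fell on that array where a rise was predicted, among them PLAT at -1.36, ARL14 at -1.12 and ABCB4 at -0.85, all 3 at background on every BT20 parental array. These values are scaled, and after scaling the 7830 genes not well above background elsewhere had a median change of -0.869 on this array. The falls of genes at background therefore count little against mixing. A mixed sample and a parental subpopulation that expresses ABCB1 cannot be told apart. The brighter genes disagree, and the median of the 24 genes lies within 0.5 of that of another parental array.

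The keratins KRT6A, KRT6C, KRT14, KRT16, KRT17 and KRT20, LY6D and SERPINB5 rose in MDA-MB-436 resistant cells, LY6D differed between the lines (F = 63.1), and the keratin list lost its call with an estimated correlation (adjusted p = 0.562). Cells or RNA of another line of the series as the whole source are argued against, since of the abundant genes of the other groups that were off in parental MDA-MB-436, at most 8.7% were on in the resistant arrays for BT20, MDA-MB-231 and MDA-MB-468 (7 to 23 genes per group). For SUM149 these were 1 of 4 genes (25%) in parental and 1 of 6 (16.7%) in resistant cells, each time KRT6C, so few genes bear on that line, but SUM149 had so little LY6D that a share of at least 5780% would be needed. A rise carried by 1 array is argued against as well, since the median of the 8 genes was 4.78 to 4.94 with each resistant array left out. A partial contribution and cells from outside the series were not tested, and a change of cell state may also give this pattern.

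The list of interferon-stimulated genes was called higher in 4 of the 5 lines, but with an estimated correlation in BT20 only (adjusted p = 0.188 in MDA-MB-231, 0.692 in MDA-MB-436 and 0.562 in MDA-MB-468), and 16 and 12 of 42 members passed in MDA-MB-436 and MDA-MB-468. The row of the slide is argued against in BT20, where the list's median was 2.04 with the row as a term and 2.02 without it. Scaling is argued against, since the list's median exceeded that of all tested genes by at least 0.6 in each of the 4 lines. In MDA-MB-231, MDA-MB-436 and MDA-MB-468 the row and the state cannot be told apart, because in 0 of these 3 lines a state lay in both rows. A response to the resistant state may explain the pattern, and so may any difference in handling that followed the state, which was not tested.

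Genes of other BT20 arrays lay apart from their group as follows: SPDEF (0.833) and RTL8B (0.889) on parental 1, RTP4 (0.864) and SPDEF (0.841) on resistant 2, ISG20 (0.91), CTHRC1 (0.89) and OLFM4 (0.917) on resistant 1. DPYSL5 (0.859) lay apart on resistant 4, where the gene was at background on all 4 arrays. In SUM149 these were TMC8 (0.946) and CFI (0.87) on parental 1, RYR2 (0.886) and CXCL8 (0.904) on parental 2, and INHBA (0.843), CFI (0.916) and CA9 (0.877) on resistant 2. In MDA-MB-231 they were RTP4 (0.854), BICD1 (0.893) and GNG11 (0.894) on parental 1, HOXB6 (0.862) on parental 2, CXCL8 (0.862) on resistant 3 and SORCS2 (0.911) on resistant 1. The 75th percentile of the MDA-MB-231 resistant 1 array (0.902) was 1476.9, against 1286.7 to 1305.4 on the others. In MDA-MB-436 they were NOG on parental 2 (0.862) and resistant 2 (0.836), and ZNF22 on resistant 3 (0.838).

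The change between states differed between the lines for 15281 genes. Of the 36 genes named in the comparison across lines, 33 differed and TNFSF9, HOXB6 and NOG did not pass that test. Among genes higher in 3 or more lines, F was 8.42 for ABCB1, 4.5 for HERC6, 6.64 for RTP4, 8.82 for INHBA, 5.65 for TMC8, 15.1 for LAMP3, 12 for PCDHB14, 4.97 for ISG20, 17.4 for CTHRC1 and 9.61 for CLDN1. For ABCB1 the parental signals were at background in 4 lines, so its F does not show that the size of the rise differed, and the same holds for ABCB4 (32.5), at background in the parental cells of the 3 lines tested. F was 30.7 for RYR2, 20.1 for CXCL8, 19.4 for SORCS2, 7.11 for SERPINB3, 7.89 for SERPINB4 and 10.4 for BDKRB1. Among genes lower in 3 or more lines, F was 29.4 for CFI, 11.2 for SPDEF, 22.6 for CA9, 26 for ABAT, 17.8 for OLFM4, 41.8 for CPVL, 86.2 for RBPMS, 38.4 for RTL8B and 5.36 for BICD1. Among genes changed in opposite directions, F was 783 for ZNF22, 361 for GNG11, 263 for DPYSL5, 168 for AHR, 135 for BST2 and 126 for VIPR1.

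Other splits of the arrays of each line into groups of the same size were counted. Over all 35 splits chance can be excluded for the genes called in MDA-MB-436 (5422, highest other split 14), with 1 split as large, the real one. The real split was also the only one as large in BT20 (5250, highest other 2017). Pairs with the same number correlated at 0.09 to 0.33 there, the own number being highest for all 4. So the 8 BT20 splits that part all 4 pairs, with a highest other of 458, are too few for a share under 0.05. In SUM149 (3669) and MDA-MB-231 (9650) pairs with the same number correlated above 0.1 for all 4 numbers, so the replicate numbers may pair the samples. This is less clear in MDA-MB-231, where number 3 correlated at 0.18 with its own number and 0.2 with another. If they are pairs, the 8 splits that part all 4, as the real one does, are too few for a share under 0.05. The highest others of these were 2 and 3513. The other splits leave pairs together and called at most 9 and 3625. The BT20 split that follows the rows of the slide called 458. The 10 splits of MDA-MB-468 (4730, highest other 411, and 23 among the 4 that part all pairs) and the 16 sign patterns of the 5 lines as replicates (2, highest other 0) are too few for a share under 0.05. Over 100 splits drawn within lines, only the real one gave 182 shared genes or 15281 genes that differ between lines. The highest others were 2 and 6890 where the states were exchanged only within pairs in SUM149, MDA-MB-231 and MDA-MB-468, and 0 and 3484 without regard to the pairs. Such splits take away most of the difference between states within each line. They therefore bear on that difference, and cannot decide whether the sharing or the differences between lines exceed chance. The count of 45 gene lists was reached by no other split, but by a narrow margin, with highest others of 43 and 42 and medians of 29 and 28. Chance is thereby not excluded for any single list, and 4 lists were called with an estimated correlation.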

How the results depend on the processing

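The row of the slide as a term in BT20, the shared genes, the genes that differ and the gene lists without MDA-MB-231, and MDA-MB-231 genes well above background on all 38 arrays were chosen after the data had been seen, and the other alternatives before. ABCB1 kept its direction and its side of the threshold under every alternative run in all 5 lines, with log2 fold changes of 6.18 to 9 in BT20, 6.66 to 10.63 in SUM149, 3.33 to 6.84 in MDA-MB-231, 3.82 to 6.98 in MDA-MB-436 and 5.02 to 7.68 in MDA-MB-468 and a highest adjusted p of 0.00233. The lowest came with normexp background correction, whose offset of 50 compresses low signals by construction, and ABCB1 was not tested under the stricter filter, since parental arrays were at background. Signal over background limits the folds of such genes to lower bounds.

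Counts of called genes stayed within 1.5 times the reported count under 10 of 12 alternatives in BT20, 10 of 11 in SUM149, 12 of 12 in MDA-MB-231, 11 of 11 in MDA-MB-436 and 10 of 11 in MDA-MB-468. With each line fitted with its own 2 groups the counts were 3084 in BT20, 6742 in SUM149 and 2605 in MDA-MB-468, and each fit then had its own spread and fewer arrays. With the row of the slide as a term BT20 gave 1808, from the fit of 3084, where 3 of 4 arrays of each state share a row, so that the term widens the error by construction. The replicate block, the replicate number within each line, gave 6096 genes in BT20, 4408 in SUM149, 10639 in MDA-MB-231, 6183 in MDA-MB-436 and 5516 in MDA-MB-468. A slide block was not run separately, since each line had its own slide and the line terms carry it.

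The 182 genes shared by 3 or more lines became 76 with normexp background correction, 94 with genes well above background on every array of both groups and 85 without MDA-MB-231. The count was 1020 with no smallest fold and 26 with 4-fold or more, as a looser or stricter limit gives by construction. For normexp the cause was not tested. The fewer genes tested under the stricter filter, and the fewer lines, lower the count by construction.

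With the 5 lines as replicates limma called 2 genes, and 1189 had an unadjusted p under 0.05. It called 0 with normexp background correction, quantile normalization, no filter on dim genes or eBayes with trend and robust, and 1 with genes well above background on every array of both groups. It called 0 without BT20, MDA-MB-231, MDA-MB-436 or MDA-MB-468 and 1 without SUM149, where fewer lines leave a weaker test. The stricter filter leaves out ABCB1, 1 of the 2 genes, by construction, and the cause was not tested for the other settings.

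Of the 45 gene lists called, 4 were called with an estimated correlation, which by construction widens the test for lists whose members vary together, and fry in place of camera called 70. The median around ABCB1 in BT20 was 0.28 in a window of 5 Mb, with a share of 0.116, and kept its side of the threshold under 4 of 5 alternatives. The other 4 lines kept theirs under 5 of 5. The genes whose change differs between the lines ran from 12436 to 16377, within 1.5 times the reported count. The median correlation between lines ran from 0.03 to 0.05. It stayed within the error of the reported median, estimated by leaving out each array in turn (a jackknife).

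Leaving out each array in turn gave 4186 to 5341 genes in BT20, 2557 to 3802 in SUM149, 8130 to 9916 in MDA-MB-231, 4691 to 5023 in MDA-MB-436 and 3665 to 5202 in MDA-MB-468. It gave 168 to 210 shared genes, 14600 to 15878 that differ between lines and 42 to 49 lists. The ABCB1 change ran from 8.6 to 10.14, 10.55 to 10.71, 6.41 to 6.98, 6.77 to 7.01 and 7.44 to 7.79 in the order of lines above. With the 5 lines as replicates the count ran from 0 to 2. It was 0 without BT20 parental 2, and 1 without BT20 resistant 1, BT20 resistant 2, MDA-MB-436 parental 2, MDA-MB-468 parental 2 or MDA-MB-468 resistant 1.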

Other observations

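Further members of the gene lists also changed, chosen here after their values were seen. CXCR4, a chemokine receptor, was at least 43.1-fold lower in BT20 resistant cells. MAPT, which encodes the microtubule-binding protein tau, changed by 2.51 ± 0.38 in BT20 (well above background on 1 of 4 parental arrays), 1.99 ± 0.38 in MDA-MB-231 and -1.64 ± 0.38 in MDA-MB-436. AGR2, a secretory pathway protein, changed by -4.64 ± 0.42 in MDA-MB-231, 3.57 ± 0.49 in MDA-MB-468 and 2.13 ± 0.42 in BT20. MAGEC1, a cancer-testis gene, changed by -6.57 ± 0.55 in MDA-MB-231 (well above background on 2 of 4 resistant arrays) and -4.17 ± 0.55 in MDA-MB-436. The antiproliferative gene BTG2 rose by 3.41 and CHGA (chromogranin A) by 3.47 in MDA-MB-468. ALDH1A3 changed by -3.53 and ABCA13 by 3.17 in MDA-MB-436, and DCLK1 by 3.52 and EGF by 3.31 in BT20. CHGA was well above background on 1 of 3 parental arrays, ABCA13 on 2 of 4 and DCLK1 on 1 of 4, so these sizes are rough.

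Some genes that fell steeply lie near each other, which could follow from loss of the genome segment that holds both genes. The pairs were noticed in the data, and the tests were run on the same data. Loss of the segment would take both genes and every gene in between to background. A gene is said to have kept its level if it was not called lower and changed by under 1 (log2), which does not show that it was unchanged. In MDA-MB-436 BZW2 and OCIAD2 fell but stayed well above background on 4 of 4 resistant arrays and AHR on 1 of 4. Between BZW2 and AHR, 1 of 2 expressed genes kept its level, AGR2 at 0.01, and TSPAN13 was -0.66. Between SLC10A4 and OCIAD2, 1 of 3 expressed genes kept its level, ZAR1 at -0.02, while FRYL was -0.63 and OCIAD1 -0.93. Between GNG11 and SDHAF3, both at background in MDA-MB-468 resistant cells, 2 of 9 expressed genes kept their level, PEG10 at -0.37 ± 0.42 and PON2 at -0.40 ± 0.33. All 9 changes were negative, and 3 genes were called lower by 2-fold or more: SGCE at -1.20, SLC25A13 at -1.34 and SEM1 at -1.29. Between FMR1NB and PASD1, both at background in BT20 resistant cells, 6 of 14 expressed genes kept their level and 5 were lower by 2-fold or more, among them MTMR1 at least 69.7-fold lower and HMGB3 at -2.01. A loss of all copies of the whole segment is argued against for each pair by the genes that kept their level. These stayed well above background on every resistant array of the line. Losses of smaller parts stay open, and a loss of only some copies was not tested.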
